A study of Homo sapiens with 9 samples.

How the data were processed

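Expression was measured in HepG2, an established human cell line derived from a hepatocellular carcinoma. Total RNA from 9 samples was used for stranded libraries depleted of ribosomal RNA, per the labels' protocols. Per the labels, 3 samples (WT) were controls kept in RPMI medium. A further 3 samples (DNL, a model of de novo lipogenesis) received DMEM with 10 µg/ml insulin and 10 µM T0901317, an agonist of the liver X receptors (LXR), for 1 week. The last 3 samples (OA) received DMEM with 25 µM oleic acid, carried in 11% bovine serum albumin, for 6 hours. No sample received this albumin without oleic acid, so effects of the carrier are not separated from those of oleic acid. Every medium held 10% serum and 1% antibiotics. A general protocol field repeats the DNL recipe for every sample, so groups were taken from the sample titles and the treatment of each sample from its own treatment label. Added compounds and duration differ together between DNL and OA, and medium too between each of them and WT, and no comparison separates what differs.

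The deposited table held estimated counts per gene, which the authors made with kallisto 0.48.0 after quality control with FastQC 0.11.9 on the GRCh38 build, per the submitters' processing notes. The annotation release behind the counts, and whether kallisto was told the strand, are not given in the sources used here. Reads of overlapping genes and of near-identical gene copies may therefore be split between them by the estimator. The table had 19317 Ensembl gene identifiers, of which 19316 were matched to a symbol and 19272 to GENCODE release 29, the source of all coordinates printed. In GENCODE release 29, 19218 of them are protein coding. All 9 libraries had a count of 0 for 2287 genes. Totals over the listed genes ran from 7836520 to 43043347 per library. A count of 3, the limit that a count of 0 allows, corresponded to 0.0697 CPM in the deepest library and 0.383 CPM in the shallowest. These limits cover counting error only, since the reads carry no molecular identifiers as far as the sources used here say.

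Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled by the trimmed mean of M values (TMM), and tested with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp and glmQLFit, both robust, then glmQLFTest) in R 4.3.3. A single fit of all 9 samples with the group as the only factor gave all 3 comparisons over 13636 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.0112, a coefficient of variation of 10.6% between replicates. Levels are TMM-scaled counts at a common library total (CPM), as mean ± SD over 3 samples, and SE is the standard error of a log2 fold change, derived from the F statistic. A fold against a group with no counts was computed against a floor of 3 counts over that group and is a lower bound for counting error only. A count of 0 may also come from how the estimator split reads between overlapping genes or near-identical copies, which the bound does not cover. With 1 to 3 counts in the lower group, an exact 95% interval of the ratio of summed counts is given, which covers counting error only.

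The 38 gene lists were tested with camera and its preset correlation between genes, with Benjamini-Hochberg adjustment over the lists within a comparison, and again with an estimated correlation and with fry (limma 3.58.1). The preset correlation takes no account of how strongly a list's genes vary together between these samples, and groupings that mix the treatments 2 to 1, which keep part of the difference between them, also gave called lists. The lists, 16 sentinel genes, the groups, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule for named genes had 3 parts. The first took, per comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group, no overlap between the 3 values of each group, and a symbol that is no clone or locus name. Chance alone gives no overlap for 10% of unchanged genes with 3 samples against 3. The second part took the sentinel genes, and the third took up to 4 members per described list, the 2 with the smallest adjusted p in each direction, or 4 of 1 direction where the other had none. Genes outside this rule are marked in the text as chosen after their values were seen.

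No label says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 5.44 and 16.6, and none was treated as a duplicate.

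The procedure was tested on simulated counts with 200 changed genes drawn from the real means, dispersions and library sizes. For DNL against WT, over 13466 genes, 87.5% of 4-fold, 67.6% of 2-fold and 60% of 1.5-fold changes were recovered, and 8.33% of calls were false. For OA against WT, over 13462 genes, the shares were 89.0%, 74.0% and 55.1%, with 9.88% false calls. For DNL against OA, over 13461 genes, they were 91.8%, 77.0% and 64%, with 5.46% false calls. False calls in these single simulations thus exceeded the nominal share. That share cannot be carried over to the calls printed here, since only 200 genes were changed. The real comparisons called 7342 genes for DNL against WT, 8188 for OA against WT and 8557 for DNL against OA. The share of false calls among them was not measured. A first requirement that over 90% of 4-fold changes be recovered was not met and was dropped after this was seen. The requirement kept is a median error of the log2 fold change under 0.1. A list of 20 genes raised 1.5-fold was called in each comparison. Among 20 random lists, 1 was called in each comparison. After that result, 20 further lists without changed genes were drawn, of which 0 were called by camera. Simulated genes were drawn independently, so these lists do not test how camera treats genes that vary together. In DNL against WT the estimated correlation was 0.879 for mitochondrially encoded transcripts and 0.5 for cytosolic ribosomal proteins.

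Alternatives were other tests (DESeq2 1.42.0, limma-voom), scalings, count filters, sets of genes and samples, a non-robust fit, a replicate block, stricter thresholds and the omission of each sample in turn. Removal of a trend with GC content and gene length, omission of 37 uneven transcripts described in the results, and a list of genes with stable levels across the OA libraries were chosen after seeing the data. Results of a few genes named by the rule are not reported here.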

Results

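The study compared the transcriptomes of HepG2 cells in 2 models of steatosis with those of control cells. Each of the 3 groups had 3 samples. Total estimated counts over the listed genes were 16447398 to 36147431 in DNL, 7836520 to 28636903 in OA and 26425694 to 43043347 in WT. OA replicates 3 and 1, with totals of 7836520 and 11718261, were the shallowest libraries. Libraries separated by group, with the lowest correlation within a group at 0.965 (OA) and the highest between groups at 0.954. The 20 most abundant genes took 19.6% ± 0.344 of counts in DNL, 9.06% ± 0.246 in OA and 13.2% ± 0.292 in WT (SD, n = 3). Mitochondrially encoded transcripts took 5.93% ± 0.689, 3.39% ± 0.189 and 3.22% ± 0.319.

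The comparison of DNL with WT asks what the lipogenic medium changed. Genes of fatty acid synthesis, cholesterol synthesis, LXR signalling, glycolysis and the hypoxia response were higher in DNL. SCD, the stearoyl-CoA desaturase (chromosome 10, 100347124 to 100364834), rose from 1019 ± 31.7 to 12330 ± 186 CPM (log2 fold change 3.60, SE 0.0619, adjusted p = 4.31e-13). FASN, the fatty acid synthase, rose from 1053 ± 21.01 to 6582 ± 104 CPM, a 6.25-fold difference. ABCG1, a cholesterol exporter and LXR target (chromosome 21, 42199689 to 42297244), rose from 0.156 ± 0.135 to 75.1 ± 5.18 CPM. In all, 3692 genes were higher and 3650 lower in DNL than in WT among 13636 tested, of which 983 and 692 changed at least 2-fold.

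**Figure D1:**
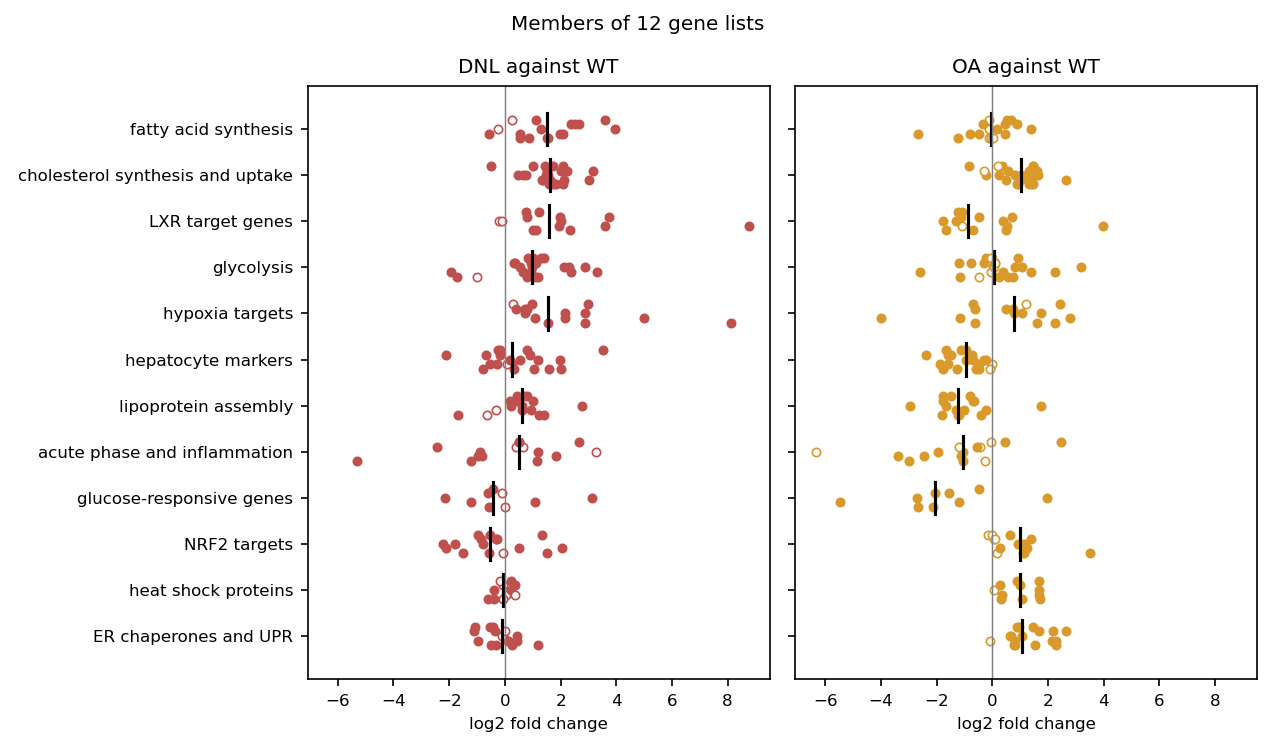
Log2 fold changes of the members of 12 gene lists in DNL against WT (left) and OA against WT (right). Each point is a gene, filled where its adjusted p was under 0.05, and the black bar is the list median, which for fatty acid synthesis is 1.52 in DNL and -0.05 in OA.

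Of 17 fatty acid synthesis genes tested in DNL against WT, 14 rose and 1 fell, and the counts adjusted over the list alone were also 14 and 1 (camera adjusted p = 3.71e-43). FADS2, a fatty acid desaturase, rose from 42.8 ± 1.52 to 669 ± 22.5 CPM. ACACA, the acetyl-CoA carboxylase, rose 2.93-fold. MLXIPL, which encodes the carbohydrate response factor ChREBP, was the member that fell, from 269 ± 12.8 to 180 ± 3.67 CPM. Of 25 genes of cholesterol synthesis and uptake, 24 rose and 1 fell (24 and 1 adjusted over the list alone; adjusted p = 5.69e-43). HMGCS1 rose from 117 ± 4.38 to 475 ± 12.8 CPM and DHCR7 from 121 ± 3.17 to 531 ± 13.1 CPM. PMVK fell by 0.49 on the log2 scale. The call of PMVK was lost without DNL replicate 2 (adjusted p = 0.0588) and without WT replicate 1 (adjusted p = 0.0611).

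Of 14 LXR target genes, 12 rose and 0 fell in DNL against WT (12 and 0 adjusted over the list alone; adjusted p = 2.28e-26). MYLIP, which encodes a ubiquitin ligase, rose from 4.53 ± 0.228 to 59.8 ± 3.31 CPM. SREBF1, the transcription factor of lipogenesis, rose from 78.6 ± 1.44 to 310 ± 11.1 CPM, LPCAT3 from 53.8 ± 2.78 to 216 ± 13.4 CPM and ABCA1 from 476 ± 7.34 to 1033 ± 39.2 CPM. Of 24 glycolysis genes, 21 rose and 2 fell (21 and 2 adjusted over the list alone; adjusted p = 3.62e-20). The glucose transporter SLC2A3 rose from 86.8 ± 5.08 to 429 ± 11.3 CPM and ALDOC from 5.69 ± 0.165 to 56.2 ± 4.99 CPM, while SLC2A2 and PFKP fell by 1.92 and 1.74 on the log2 scale. Of 15 hypoxia targets, 14 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 6.38e-18). NDRG1 rose from 23.4 ± 0.919 to 184 ± 12.1 CPM, ADM from 9.53 ± 0.889 to 69.6 ± 3.15 CPM and PFKFB4 from 7.62 ± 0.784 to 55.9 ± 2.57 CPM. These 5 lists were also called with an estimated correlation, at adjusted p = 0.000563, 0.00281, 0.000563, 0.000563 and 0.0164 in the order given.

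The other 13 called lists of DNL against WT lost the call with an estimated correlation. In all 18 called lists the counts adjusted over the list alone equalled those over all genes, except that lipoprotein assembly had 2 lower members instead of 1 and gluconeogenesis 4 higher members instead of 3. Of 22 ATF4 targets of the amino acid response, 20 fell and 0 rose (adjusted p = 4.51e-12, and adjusted p = 0.115 with an estimated correlation). CTH fell from 104 ± 3.31 to 24.4 ± 0.643 CPM and ASNS from 383 ± 11.1 to 212 ± 4.05 CPM. Of 16 NRF2 targets, 11 fell and 4 rose (adjusted p = 0.000136, and adjusted p = 0.109 with an estimated correlation). GCLC and AKR1C1 fell by 1.79 and 2.13 on the log2 scale, while GPX2 rose. The lists of ketone body metabolism (5 of 6 fell, 1 rose), gluconeogenesis and insulin-repressed genes (7 of 11 fell, 3 rose) and immediate early genes (11 of 16 fell, 4 rose) were lower. Their adjusted p with an estimated correlation was 0.109, 0.141 and 0.474. IGFBP1, which insulin represses, fell from 5147 ± 184 to 1827 ± 52.7 CPM.

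Hepatocyte markers were called higher in DNL than in WT, with 12 of 21 members higher and 8 lower, and adjusted p = 0.264 with an estimated correlation. TF, the transferrin gene, rose from 544 ± 15.3 to 6279 ± 146 CPM and SERPINA1 from 2072 ± 89.2 to 8139 ± 315 CPM, while TAT and FOXA1 fell by 2.12 and 0.54 on the log2 scale. Lipoprotein assembly genes rose in 13 of 16 cases and fell in 1, with adjusted p = 0.126 with an estimated correlation, and APOA1 rose from 543 ± 24.5 to 1449 ± 21.4 CPM. Also called higher were pentose phosphate and NADPH supply (5 of 9 rose, 2 fell), bile acid synthesis and transport (6 of 14 rose, 2 fell), interferon-stimulated genes (9 of 14 rose, 2 fell) and mitochondrially encoded transcripts (10 of 13 rose, 1 fell). With an estimated correlation their adjusted p was 0.147, 0.297, 0.145 and 0.662. The last 3 of these stood at adjusted p = 0.0492 and lost the call with RLE size factors (adjusted p = 0.0509 for each) and without single libraries, as follows. Bile acid genes lost it without DNL replicates 1, 2 or 3 (adjusted p = 0.0567, 0.056 and 0.0747) or OA replicate 1 (0.0603), and interferon-stimulated genes without OA replicates 1 or 3 (0.0603 and 0.0511). Mitochondrially encoded transcripts lost it without DNL replicate 2 (0.0673), OA replicates 1, 2 or 3 (0.0952, 0.0672 and 0.0787) or WT replicate 2 (0.061), and pentose phosphate genes with scaling by library totals (0.0689). Removal of the GC content and length trend ended the calls of mitochondrially encoded transcripts and interferon-stimulated genes (adjusted p = 0.105 and 0.053), and omission of the 37 uneven transcripts those of bile acid genes and mitochondrially encoded transcripts (0.0523 and 0.0528).

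Markers of other cell types were also measured. The macrophage and leukocyte list had 3 of 5 genes higher and 1 lower in DNL than in WT (adjusted p = 0.0521 with an estimated correlation), where CD74 rose from 29.2 ± 1.14 to 187 ± 8.41 CPM. The cholangiocyte list had 5 of 6 genes higher (adjusted p = 0.115 with an estimated correlation), with SOX9 at 320 ± 8.13 CPM in WT and 662 ± 28.6 CPM in DNL. The remaining 20 lists were not called. Among them, all 3 endothelial markers tested were higher (adjusted p = 0.265), at low levels, with VWF at most 3.99 CPM in a DNL library. Of 9 fibroblast markers, 0 were higher and 1 was lower (adjusted p = 0.542). Glucose-responsive genes (5 of 9 lower, 2 higher, adjusted p = 0.0557) were called lower without OA replicates 1 or 2 (adjusted p = 0.0241 and 0.029), and cytosolic ribosomal proteins (11 of 28 lower, 3 higher, 0.201) with scaling by library totals (0.0453). Among these 20, the median, mean and test of the lipid droplet, extracellular matrix, histone and adipocyte lists differed in sign. Regrouping the same 6 samples so that each side held 2 samples of a group and 1 of the other gave up to 11 called lists with the preset correlation, and 0 genes.

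The largest rises in DNL against WT were CCND2, PPT2, LCN15, ABCG1, CA9 and PANK4. CCND2, which encodes cyclin D2 (chromosome 12, 4273772 to 4305350), had 1 count over the WT group and 176 ± 10.3 CPM in DNL, a ratio of counts between 3115 and 685600. PPT2 and LCN15 had no counts in WT and were at least 356-fold and 220-fold higher, as bounds for counting error only. PPT2 was uneven in DNL, at 7.24, 21.2 and 8.64 CPM. CA9, a carbonic anhydrase induced by hypoxia, rose from 0.0718 ± 0.0732 to 20.7 ± 2.28 CPM. PANK4 rose from 0.141 ± 0.122 to 17.24 ± 0.4803 CPM, without a call in limma-voom (adjusted p = 0.131). Its level was uneven in OA, at 14.0, 0.165 and 12.8 CPM in replicates 1, 2 and 3. The largest falls were AQP3, C5AR1, KLHDC7B, ACTA1, DEPP1 and FAM43A. AQP3, an aquaporin that carries glycerol, fell from 222 ± 8.09 to 0.806 ± 0.493 CPM, and C5AR1 from 70.6 ± 1.82 to 2.90 ± 0.385 CPM.

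Values of the other sentinel genes in DNL against WT were as follows. PLIN2, which coats lipid droplets, rose 1.73-fold, CPT1A 1.39-fold, ANGPTL4 4.47-fold and ALB 1.20-fold. The call of ALB was lost when libraries were scaled by their totals (adjusted p = 0.171). TXNIP measured 243 ± 0.902 CPM in WT and 228 ± 11.6 CPM in DNL, which did not pass the test (adjusted p = 0.228) but was called lower when libraries were scaled by their totals (log2 fold change -0.26, adjusted p = 0.00564), and PDK4 had 0 counts in WT and 2 in DNL. Scaling by library totals shifted the median of all genes by -0.17 (log2), and 32.2% of calls were then higher, against 50.3% with TMM.

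**Figure D2:**
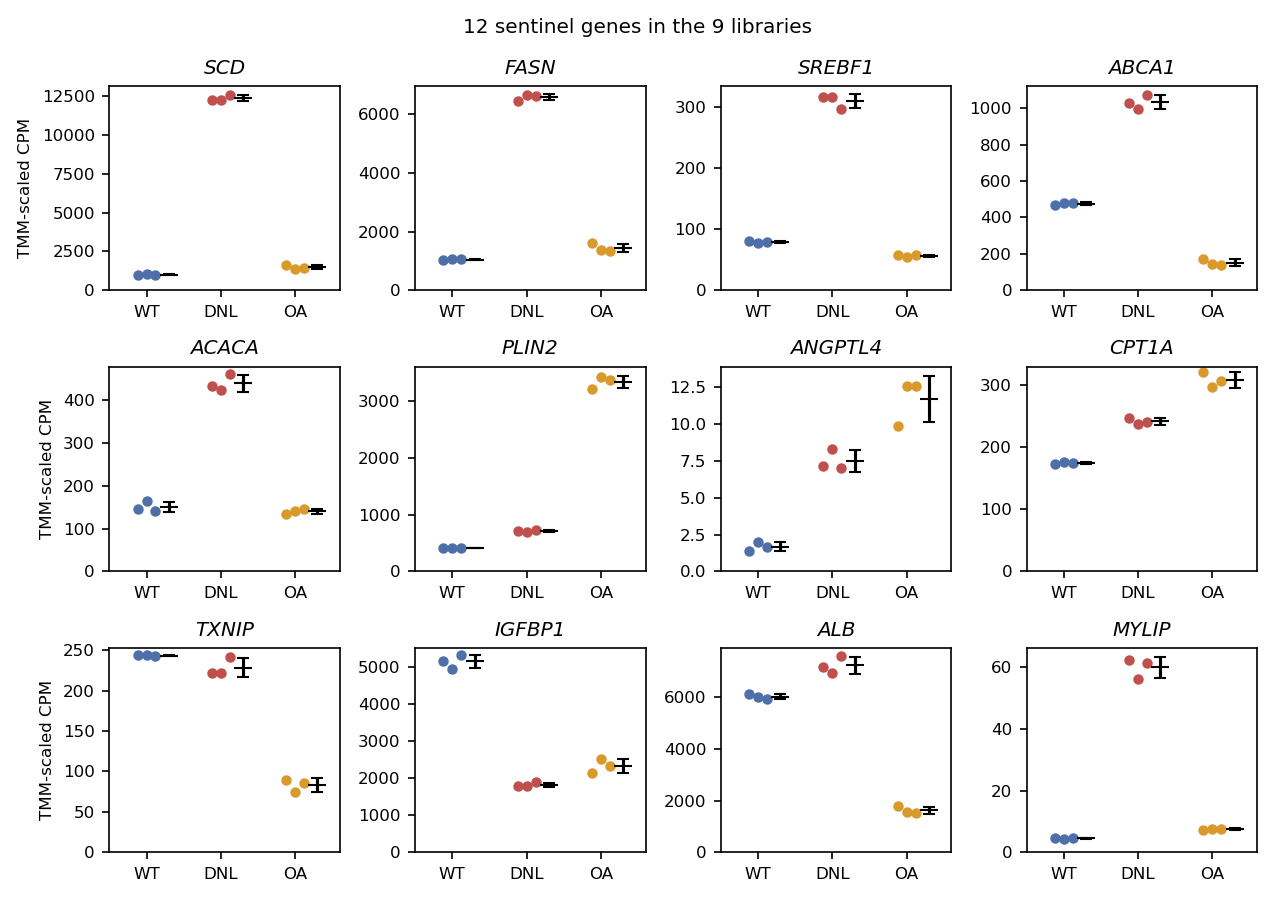
TMM-scaled CPM of 12 sentinel genes in the 3 libraries of each group, with the mean and SD beside the points. SCD and FASN are highest in DNL, while PLIN2 is at 3342 ± 112 CPM in OA.

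The comparison of OA with WT asks what differed in cells kept in the fatty acid medium. The samples include no earlier time point and no DMEM culture without added compounds, so when the differences arose was not tested. PLIN2 (chromosome 9, 19108375 to 19149290) rose from 412 ± 3.53 to 3342 ± 112 CPM (log2 fold change 3.02, SE 0.0398, adjusted p = 7.88e-14). Chaperones of the endoplasmic reticulum, NRF2 targets and cholesterol synthesis genes were higher in OA, and hepatocyte markers, lipoprotein genes and glucose-responsive genes were lower. HSPA5, the chaperone BiP, rose from 1049 ± 20.6 to 4723 ± 261 CPM. ALB fell from 6015 ± 101 to 1628 ± 139 CPM. In all, 4139 genes were higher and 4049 lower in OA than in WT, of which 1211 and 1084 changed at least 2-fold.

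Of 17 genes of the unfolded protein response, 16 rose and 0 fell in OA against WT (16 and 0 adjusted over the list alone; adjusted p = 4.22e-27). CALR rose from 448 ± 14.6 to 1317 ± 24.8 CPM and DNAJB9 from 86.8 ± 2.19 to 279 ± 9.99 CPM. Of 25 cholesterol genes, 21 rose and 2 fell (21 and 3 adjusted over the list alone; adjusted p = 1.79e-14). Of 16 NRF2 targets, 11 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 5.69e-10). HMOX1, the haem oxygenase, rose from 14.9 ± 1.91 to 169 ± 21.9 CPM and TXNRD1 from 608 ± 23.3 to 1352 ± 95.1 CPM. Of 18 genes of lysosome and autophagy, 14 rose and 2 fell (adjusted p = 0.000831), with SQSTM1 3.17-fold higher and CTSD at a log2 fold change of -0.51. These 4 lists held with an estimated correlation, at adjusted p = 0.0159, 0.0302, 0.0302 and 0.0357.

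Of 21 hepatocyte markers, 19 fell and 0 rose in OA against WT (19 and 0 adjusted over the list alone; adjusted p = 5.68e-18). AHSG fell from 2659 ± 14.1 to 1112 ± 37.6 CPM and RBP4 from 699 ± 14.5 to 230 ± 12.1 CPM. Cholangiocyte markers, with 3 of 6 higher and 1 lower, were not called (adjusted p = 0.0852). They were called higher without OA replicate 3 (adjusted p = 0.0263), without DNL replicates 1 or 3 (0.0415 and 0.03) and after removal of the GC content and length trend (0.0439). KRT19, chosen after its values were seen, rose from 92.2 ± 2.97 to 551 ± 60.3 CPM, and SOX9 fell from 320 ± 8.13 to 254 ± 15.0 CPM. KRT7, a higher member also chosen after its values were seen, belongs to the uneven transcripts described below. It measured 0.474, 1.48 and 8.19 CPM in OA replicates 1, 2 and 3. Of 16 lipoprotein genes, 15 fell and 1 rose (adjusted p = 1.18e-11). APOB, the structural protein of very low density lipoprotein, fell from 30210 ± 782 to 8768 ± 748 CPM, while APOA4 rose. Of 9 glucose-responsive genes, 8 fell and 1 rose (adjusted p = 1.79e-14). G6PC1, the catalytic subunit of glucose-6-phosphatase, fell from 79.3 ± 1.73 to 1.82 ± 0.0771 CPM, and TXNIP from 243 ± 0.902 to 83.3 ± 8.11 CPM. PPP1R3B was the member that rose, from 0.292 ± 0.123 to 1.32 ± 1.02 CPM, and its call was lost without OA replicate 3 (adjusted p = 0.117), OA replicate 1 (0.061), WT replicate 2 (0.071) or WT replicate 3 (0.0558) and in limma-voom (0.169). Acute phase genes (8 of 15 fell, 2 rose), gluconeogenesis genes (6 of 11 fell, 3 rose) and bile acid genes (11 of 14 fell, 1 rose) were lower. HP fell from 164 ± 8.58 to 16.1 ± 2.34 CPM, PCK2 from 366 ± 4.51 to 76.1 ± 1.15 CPM and NR1H4, the bile acid receptor, from 43.6 ± 3.21 to 3.60 ± 0.793 CPM. CXCL8 in the acute phase list rose from 10.2 ± 0.654 to 57.0 ± 8.64 CPM. The 6 called lists held with an estimated correlation, at adjusted p = 0.0302, 0.0257, 0.0159, 0.0302, 0.0357 and 0.0459.

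The other 10 called lists of OA against WT lost the call with an estimated correlation. Among all 20 called lists, the counts adjusted over the list alone differed from those over all genes for cholesterol and NRF2 genes, as given, and for histone genes (13 higher instead of 12). Heat shock proteins (10 of 11 rose), proliferation genes (21 of 26 rose) and histone genes (12 of 14 rose) had adjusted p = 0.0763, 0.0763 and 0.17 with an estimated correlation. HSPA8 rose from 1092 ± 45.8 to 2269 ± 107 CPM, MKI67 from 68.2 ± 3.91 to 183 ± 3.69 CPM and H4C8 from 10.7 ± 0.533 to 45.4 ± 2.21 CPM. Cytosolic ribosomal proteins fell in 23 of 28 cases, with adjusted p = 0.4 with an estimated correlation, and RPL37 fell by 0.85 on the log2 scale. Ribosomal protein and histone genes have near-identical copies, so their counts are uncertain. Fetal liver genes (6 of 10 fell, 1 rose), ATF4 targets (10 of 22 fell, 5 rose), triacylglycerol synthesis (11 of 18 fell, 5 rose) and ketone body metabolism (3 of 6 fell, 1 rose) had adjusted p = 0.114, 0.352, 0.114 and 0.153 with an estimated correlation. GPAM fell from 825 ± 20.2 to 158 ± 14.9 CPM, whereas LPIN1 rose from 34.5 ± 0.624 to 90.6 ± 3.13 CPM. Ketone body metabolism lost its call without OA replicate 1 (adjusted p = 0.0689), OA replicate 2 (0.0587) or WT replicate 1 (0.0515).

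In the list of lipid droplet proteins, 7 of 16 genes rose and 5 fell in OA. Its test pointed upwards (adjusted p = 0.00534, and adjusted p = 0.0988 with an estimated correlation) while its median log2 fold change was -0.31 and its mean 0.11. PLIN3 rose from 92.6 ± 2.09 to 272 ± 10.9 CPM, and PLIN5 fell from 3.45 ± 0.871 to 1.11 ± 0.138 CPM. Among immediate early genes, 8 of 16 rose and 8 fell, and the list was called upwards at adjusted p = 0.0133 (adjusted p = 0.4 with an estimated correlation) with a median of -0.001. The list of PPAR alpha targets was not called (adjusted p = 0.088), with 7 of 21 genes higher, 11 lower and a median of -0.21. PDK4, CPT1A and ANGPTL4 were among the members that rose. PDK4, a kinase that restrains glucose oxidation, had no counts in WT and 4.57 ± 0.693 CPM in OA, at least 163-fold higher. CPT1A rose 1.77-fold and ANGPTL4 7.01-fold. ABCA1 fell by 1.65 on the log2 scale and SREBF1 by 0.47, while SCD and FASN rose 1.46-fold and 1.38-fold. The remaining 18 lists were not called. LXR targets (8 of 14 lower, 5 higher, median -0.88, adjusted p = 0.0516) were called lower without DNL replicate 2 (adjusted p = 0.0448), OA replicates 1, 2 or 3 (0.0213, 0.0463 and 0.0317) or WT replicates 1, 2 or 3 (0.0415, 0.0405 and 0.0353), and after removal of the GC content and length trend (0.0388). Of these 18, the median, mean and test of the PPAR alpha, endothelial, macrophage and adipocyte lists differed in sign. Such mixed groupings of the 6 samples gave up to 17 called lists with the preset correlation, and 0 genes.

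A set of transcripts near 0 in WT and DNL was uneven across the OA libraries. By a rule chosen after seeing the data, 37 genes were called higher in OA than in WT, lay at or under 0.5 CPM in each WT and DNL library, and were at least 3 times higher in OA replicate 3 than in the other OA replicates. Summed, they reached 61.3 CPM in OA replicate 1, 212 CPM in OA replicate 2 and 1293 CPM in OA replicate 3, against at most 5.66 CPM in a DNL library and 4.26 CPM in a WT library. They include ELN, which encodes elastin, at 22.4, 91.0 and 587 CPM, and COL3A1 at 2.53, 9.36 and 66.9 CPM. COL1A1, a collagen on the list of fibroblast markers, measured 19.4, 85.0 and 537 CPM, with at most 0.990 CPM in a WT library. Of 9 fibroblast markers tested, 3 were higher and 2 lower in OA, and the list was not called (adjusted p = 0.652). PLIN2 differed 1.07-fold between its highest and lowest OA library.

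**Figure D3:**
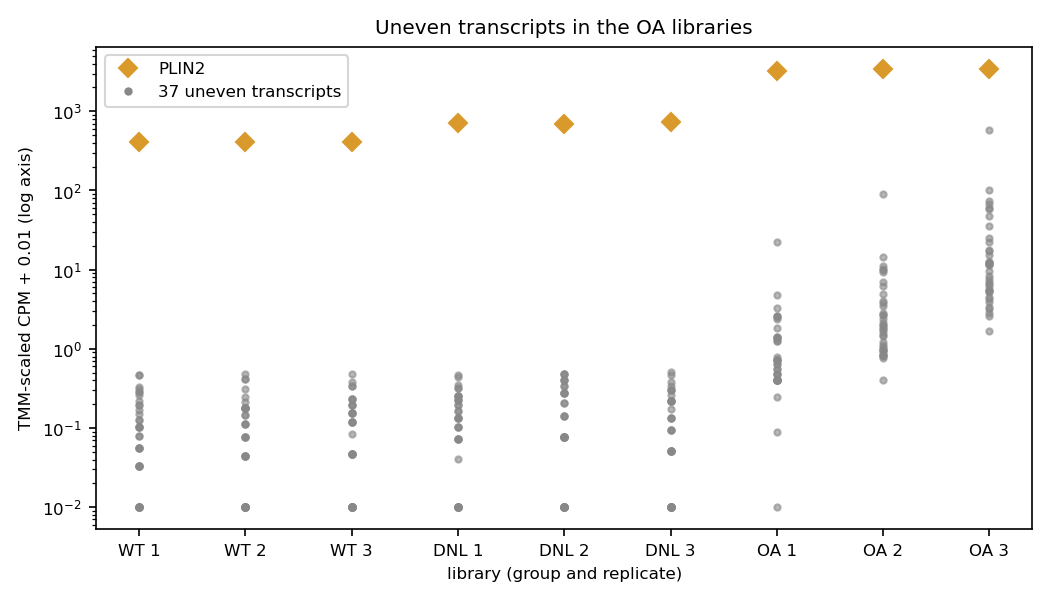
TMM-scaled CPM, with 0.01 added, of the 37 uneven transcripts (grey) and of PLIN2 (orange diamonds) in each of the 9 libraries, on a log axis. The uneven transcripts lie at or under 0.5 CPM in every WT and DNL library, and the highest, ELN, reaches 587 CPM in OA replicate 3.

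Of the 6 largest rises in OA against WT, FBN2, PXDN, COL3A1 and ELN belong to this set. HSPA6, an inducible heat shock protein, had no counts in WT and was at least 336-fold higher, at 9.39 ± 1.79 CPM in OA. ANKRD13D, at 5.31 ± 2.81 CPM, was at least 142-fold higher. The calls of these 4 uneven genes were lost in limma-voom, with adjusted p = 0.0585, 0.133, 0.117 and 0.347. The call of PXDN was also lost without any single WT replicate (adjusted p = 0.0895, 0.0849 and 0.169), and that of FBN2 without DNL replicate 3 (adjusted p = 0.0933) and in a fit of the 6 samples compared (adjusted p = 0.103). Among genes with stable levels across the OA libraries, chosen after their values were seen, KRT37 rose from 0.0384 ± 0.0665 to 9.63 ± 0.399 CPM and NDRG4 from 0.537 ± 0.335 to 30.9 ± 2.51 CPM. The largest falls were VASN, HAL, G6PC1, PTP4A3, MMP11 and ATP2B2. VASN fell from 50.8 ± 18.9 to 0.2174 ± 0.1099 CPM, and HAL, the histidine ammonia-lyase, from 31.2 ± 2.12 to 0.483 ± 0.224 CPM.

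The comparison of DNL with OA sets both models against each other in the same basal medium, with different durations and compounds. Fatty acid synthesis genes and hepatocyte markers were higher in DNL, and genes of the unfolded protein response and NRF2 targets were higher in OA. SREBF1 measured 310 ± 11.1 CPM in DNL and 57.1 ± 1.62 CPM in OA (log2 fold change 2.45, SE 0.0468, adjusted p = 4.61e-13). TF was 6279 ± 146 CPM in DNL and 279 ± 33.2 CPM in OA, whereas HSPA5 was 813 ± 20.2 and 4723 ± 261 CPM. In all, 4349 genes were higher and 4208 lower in DNL than in OA, and 1384 and 1355 differed at least 2-fold. Scaling by library totals shifted the median of all genes by -0.23 (log2), and 33.9% of calls were then higher, against 50.8%.

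Higher in DNL were 15 of 17 fatty acid synthesis genes (adjusted p = 8.61e-28), 13 of 14 LXR targets (2.77e-22), 17 of 21 hepatocyte markers (3.58e-24) and 14 of 16 lipoprotein genes (3.25e-18). Adjusted over the list alone, 16, 13, 17 and 14 members were higher. Lower members of these lists numbered 0, 1, 3 and 0. Also higher were 19 of 24 glycolysis genes (2 lower), 7 of 9 glucose-responsive genes (0 lower), 10 of 15 acute phase genes (2 lower) and 10 of 14 bile acid genes (2 lower). FADS1 was 622 ± 11.5 CPM in DNL and 200 ± 9.77 CPM in OA, LDHA 773 ± 29.8 and 254 ± 1.86 CPM, and C3 8302 ± 308 and 1799 ± 52.4 CPM. Lower in DNL were 16 of 17 genes of the unfolded protein response (1 higher; adjusted p = 2.77e-22) and 13 of 16 NRF2 targets (3 higher; adjusted p = 4.82e-16). GCLC was 120 ± 2.46 CPM in DNL and 930 ± 54.0 CPM in OA. All 10 of these lists held with an estimated correlation, at adjusted p between 0.00749 and 0.0303.

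The other 12 called lists of DNL against OA lost the call with an estimated correlation. Among all 22 called lists, the counts adjusted over the list alone differed from those over all genes for fatty acid synthesis, as given, and for histone genes (14 lower instead of 12). Heat shock (10 of 11 lower in DNL, 0 higher), histone (12 of 14, 0 higher), immediate early (12 of 16, 2 higher), proliferation (21 of 26, 0 higher) and ATF4 target genes (13 of 22, 7 higher) were called lower. With an estimated correlation, adjusted p was 0.0981, 0.193, 0.193, 0.164 and 0.452. BAG3 was 39.2 ± 0.703 CPM in DNL and 169 ± 19.4 CPM in OA. Hypoxia targets (9 of 15 higher, 1 lower), cholesterol genes (19 of 25, 0 lower), fetal liver genes (7 of 10, 3 lower) and triacylglycerol synthesis (13 of 18, 3 lower) were called higher in DNL. Their adjusted p with an estimated correlation was 0.0599, 0.15, 0.103 and 0.0981. Pentose phosphate (5 of 9 higher, 2 lower), gluconeogenesis (6 of 11 higher, 4 lower) and macrophage and leukocyte genes (3 of 5 higher, 1 lower) were called higher, with adjusted p = 0.138, 0.22 and 0.15 with an estimated correlation. These 3 lost the call with scaling by library totals (adjusted p = 0.0711, 0.0664 and 0.0657), where the median of pentose phosphate genes was -0.05. Gluconeogenesis also lost it without OA replicate 1 (adjusted p = 0.0565), and macrophage and leukocyte genes without OA replicates 1 or 3 (0.0886 and 0.058), with RLE size factors (0.0504) and after removal of the GC content and length trend (0.0765). The remaining 16 lists were not called. Mitochondrially encoded transcripts (10 of 13 higher in DNL, 1 lower, adjusted p = 0.0522) were called higher without DNL replicates 1 or 3 (adjusted p = 0.022 and 0.00408) or WT replicates 1, 2 or 3 (0.0207, 0.0494 and 0.027), with scaling by library totals (0.0257) and after removal of the GC content and length trend (0.0194). Cytosolic ribosomal proteins (17 of 28 higher, 2 lower, 0.0522) were called higher without DNL replicate 3 (0.0176), OA replicate 2 (0.0401) or WT replicates 1, 2 or 3 (0.0164, 0.0356 and 0.0441). Lipid droplet proteins (6 of 16 lower, 4 higher, adjusted p = 0.0546) were called lower without OA replicate 2 (0.0484), and lysosome and autophagy genes (9 of 18 lower, 7 higher, 0.158) with scaling by library totals (0.0268). Of these 16, the median, mean and test of the PPAR alpha, ketone body, xenobiotic, cholangiocyte and adipocyte lists differed in sign. Such mixed groupings of the 6 samples gave up to 17 called lists with the preset correlation, and at most 1 gene.

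The largest rises in DNL against OA were PPT2, PLG, PNCK, ABCG1, SLC51A and EGLN3. PLG, the plasminogen gene, was 45.1 ± 2.56 CPM in DNL and had 1 count over the OA group, a ratio of counts between 421 and 92800. SLC51A, a bile acid transporter, was 38.9 ± 3.12 CPM in DNL and had 2 counts in OA, a ratio between 271 and 8105. The largest falls were PXDN, COL5A1, ELN, ANKRD13D, MGP and AQP3, of which PXDN, COL5A1, ELN and MGP belong to the uneven set. The calls of PXDN, COL5A1 and ELN were lost in limma-voom (adjusted p = 0.132, 0.0982 and 0.349), and those of PXDN, COL5A1 and MGP in a fit of the 6 samples compared (0.136, 0.118 and 0.0555). That of PXDN was also lost without DNL replicate 1 (adjusted p = 0.0528) or WT replicates 1, 2 or 3 (0.0567, 0.057 and 0.132). AQP3 was 0.806 ± 0.493 CPM in DNL and 458 ± 33.3 CPM in OA.

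Between the comparisons with WT, 1678 genes were higher in both and 1641 lower in both, 3319 in all, while 1840 were called in opposite directions. Independent lists of these sizes would share 1121 higher and 1084 lower genes, and 2204 in opposite directions. In 20 simulations of unchanged groups that share their controls, edgeR called at most 1 gene in the same direction in both, and since unchanged groups give few calls this number says little about the overlap. The correlation of log2 fold changes across genes was 0.285, with a simulated mean of 0.460, and the covariance was 0.279, with a simulated mean of 0.0371. Simulated fold changes hold chance error only, of which the shared controls make a common part. These correlations are therefore not comparable and do not tell how alike the models are. Genes are not independent replicates. The 3 controls were not split, as a part would hold 1 library, so part of the excess may come from the shared controls. DNL and OA cells were also both in DMEM and WT cells in RPMI, and a common effect of the medium was not separated. DEPP1, among the largest falls of DNL, was also called lower in OA, from 449 ± 12.1 CPM in WT to 32.8 ± 3.92 CPM in DNL and 39.8 ± 5.85 CPM in OA.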

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

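The tests of the uneven transcripts and of the culture medium were chosen after the results were seen, while the tests of GC content, dilution and the second hypoxia list were written down before their outcomes were known.

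Effects against WT differed between DNL and OA for 3 sentinel genes and, with the preset correlation, 5 gene lists, which were called in opposite directions and also called between DNL and OA. With an estimated correlation all 5 lists lost the call in DNL against WT, at adjusted p = 0.264 for hepatocyte markers, 0.126 for lipoprotein assembly, 0.297 for bile acid genes, 0.109 for NRF2 targets and 0.474 for immediate early genes, which also lost it in OA against WT (0.4) and in DNL against OA (0.193). In OA against WT 8 immediate early genes rose and 8 fell, with a median of -0.001, so the direction of that list is unclear. The call of ALB in DNL against WT was lost with scaling by library totals (adjusted p = 0.171). The log2 difference of DNL from OA was 2.77 for ABCA1, 2.15 for ALB and 2.45 for SREBF1. As list medians it was 1.47 for hepatocyte markers, 1.67 for lipoprotein assembly, 1.64 for bile acid synthesis and transport, -1.64 for NRF2 targets and -1.33 for immediate early genes. Duration and compounds differ together between DNL and OA, and medium too against WT, so these differences name no single treatment.

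The 37 uneven transcripts of the OA libraries include genes of the extracellular matrix, such as ELN, COL3A1, COL5A1 and FBN2. The rule picked genes that were highest in OA replicate 3, so an even response over all 3 OA libraries could not be tested. The ratio of OA replicate 2 to OA replicate 1 was not used to pick them. Its median was 3.03 (interquartile range 2.09 to 3.82, over 35 genes with at least 3 counts). Among 106 other genes that rose from near 0, left after the 37 were taken out, its interquartile range was 0.955 to 1.61. For the picked genes these values argue against an even response to oleic acid between OA replicates 1 and 2 only. For the 7 PPAR alpha targets called higher in OA, the highest OA library was 1.12 times the lowest in the median. A call favours genes with even levels, so this value weighs little against an uneven exposure to oleic acid. PLIN2, a sentinel gene, differed 1.07-fold between its highest and lowest OA library. RNA or cells from another source remain open and are a candidate explanation. The lower quartile of the ratio of OA replicate 2 to OA replicate 1 was 2.09. The median ratio of raw counts was 7.25, so the libraries did not hold equal numbers of such reads, but foreign cells were not separated from RNA carried over in unequal amounts.

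The rise of hypoxia targets in DNL against WT had a list median of 1.54. A bias of GC content or gene length is argued against, since the median was 1.501 after that trend was removed. A hypothesis of a response carried by hypoxia-inducible factor is consistent with a second list of 18 of its targets, with a median of 0.59, 14 higher and 1 lower (p = 0.00342, camera with an estimated correlation). The change of medium cannot be told apart from it, since DNL cells were treated for 1 week and OA cells for 6 hours, so that neither the list in OA against WT (median 0.797, 9 higher and 5 lower, adjusted p = 0.101) nor its level in DNL against OA (median 1.25, adjusted p = 0.0599 with an estimated correlation) decides it.

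The fall of hepatocyte markers in OA against WT had a list median of -0.96. Dilution by RNA from another source is argued against only where it goes in proportion to the uneven transcripts. The medians were -0.8469, -0.9611 and -0.9969 in OA replicates 1, 2 and 3. The smaller fall was 0.85 of that in OA replicate 3, while the uneven transcripts differed over 3-fold between replicates 1 and 2. The falls did have the same order as the uneven transcripts. A dilution alike in all 3 OA libraries was not tested. A bias of GC content or gene length is argued against by a median of -0.91 after that trend was removed. The change of medium cannot be told apart from oleic acid or from the albumin that carried it. DNL, also in DMEM, had a median of 0.26 but differed in duration and compounds. No sample received the albumin alone. A response to oleic acid or to albumin stays open and untested.

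With 10 splits of 6 samples, chance cannot be given a share under 0.1. The real split was the 1 split with as many genes in each comparison. It gave 7342 genes for DNL against WT, 8188 for OA against WT and 8557 for DNL against OA, and the highest other split gave 0, 0 and 1. For gene lists it gave 18, 20 and 22, and the highest other split gave 11, 17 and 17. Each other split sets 2 samples of a group and 1 of the other against the rest. It so keeps part of the difference between the groups, and whether the lists it called come from that part was not tested. Both groups on each side also raise the spread within sides for genes that differ. Few called genes were thus likely in advance in such splits, and their number does not measure chance.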

How the results depend on the processing

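The removal of the GC content and length trend and the omission of the 37 uneven transcripts were chosen after seeing the data. The 6 counts of calls and the overlap stayed within 1.5 times their values under each alternative except the 2-fold threshold, which passes fewer genes by construction. It left 983 higher and 692 lower for DNL against WT, 1211 and 1084 for OA against WT, 1384 and 1355 for DNL against OA, and 505 in the overlap. With an estimated correlation 5, 10 and 10 lists were called in place of 18, 20 and 22. With fry, which does not compare a list with other genes, 32 and 33 were called for DNL and OA against WT. Without the uneven transcripts, OA against WT had 4116 genes higher and 4042 lower. This omission did not remove the whole pattern, since the rule required a call and low levels in WT and DNL. COL1A2, chosen after its values were seen, stayed in, at 10.19, 41.05 and 259.6 CPM in OA replicates 1, 2 and 3. Leaving out each sample in turn gave 3258 to 3869 genes higher in DNL against WT and 3765 to 4238 in OA against WT. Over all genes, deviations of same-numbered samples correlated at -0.0176 to 0.0534, against -0.063 to 0.0438 for other pairs of samples between groups. The mitochondrially encoded share, however, fell from replicate 1 to 3 in each group. It was 6.65, 5.86 and 5.28% in DNL, 3.58, 3.39 and 3.20% in OA, and 3.55, 3.18 and 2.92% in WT. A shared effect of the replicate number was thus not excluded. The replicate block moved the counts little, for example from 3692 to 3644, and named genes called in their reported direction from 289 to 288, and it ended the calls of bile acid and interferon-stimulated genes in DNL against WT (adjusted p = 0.0653 and 0.0548) and of macrophage and leukocyte genes in DNL against OA (0.055). It added 5 calls, of LXR targets, extracellular matrix genes and cholangiocyte markers in OA against WT (adjusted p = 0.0373, 0.0333 and 0.00713) and of mitochondrially encoded transcripts and ribosomal proteins in DNL against OA (3.7e-06 and 0.00835), so that 16, 23 and 23 lists were called. The extracellular matrix list holds COL3A1, COL4A1, COL5A1 and TGFB2 of the uneven set, and the cholangiocyte list holds KRT7 of that set. Whether the added calls of these lists hold without the uneven transcripts was not tested. No named gene and no called list changed direction while called. Of 295 pairs of a gene and a comparison, 58 tests over the alternatives lost and 4 gained a call, and of the 60 called pairs of a list and a comparison 68 tests lost it. Of the 54 pairs not called, 37 gained a call with fry, and 34 tests gained one under the other alternatives, run on these pairs after seeing the data. The cause of these changes was not tested. A floor of 3 counts was 0.383 CPM in OA replicate 3 and 0.256 CPM in OA replicate 1, which limits what these libraries show of low genes.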

Other observations

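The genes below were chosen after their values were seen. DNL and OA cells were both in DMEM and WT cells in RPMI, so shifts alike in both groups name no single treatment. SPARC, which encodes osteonectin, rose from 3.65 CPM in WT to 46.1 CPM in DNL and 46.9 CPM in OA. ENPP1, an ectonucleotidase, fell from 1033 CPM in WT to 157 CPM in DNL and 126 CPM in OA. COL16A1 fell from 54.3 to 9.12 and 7.62 CPM. GPD1, the cytosolic glycerol-3-phosphate dehydrogenase, fell from 81.7 to 18.5 and 12 CPM. TNS1, which encodes tensin 1, rose from 6.45 to 66.8 and 43.3 CPM.

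Some values differed sharply between replicates. PANK4 measured 14.0, 0.165 and 12.8 CPM in OA replicates 1, 2 and 3. CCND2 measured 0, 3.72 and 25.4 CPM in the same libraries.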
